A study of Mus musculus with 20 samples.

How the data were processed

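RNA was sequenced from mouse 46C cells, a line derived from E14Tg2a ESCs of the 129/Ola strain, in 4 ESC and 4 NPC libraries. Per the labels' protocols, libraries were made from 500 ng of RNA with a stranded kit that removes ribosomal RNA, and sequenced as paired reads of 151 bp. NPCs were collected at day 5, with Sox1-GFP checked by flow cytometry. The labels also hold 12 CUT&RUN samples (H3K27me3, H3K9me3 and IgG, 2 replicates each in ESCs and NPCs, 100000 cells per assay), which were not analysed here, and neither were repeat elements.

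The authors deposited TPM values per gene for each library. TPM corrects counts for gene length and scales each library to 1000000, so a rise of abundant genes lowers all others. Per the submitters' processing notes, Trim Galore 0.4.1, STAR, bedtools, HTSeq and DESeq2 were used with the mouse build mm10; their roles, settings and other versions are not given in the sources used here. The authors' deposited table also gives, per the file headers, a mean signal over samples (baseMean), a log2 fold change of NPC over ESC with its error, and a p-value with its adjusted value, under column names that DESeq2 uses. For 83.6% of genes the authors' deposited log2 fold change divided by its error gives a larger p than the p-value beside it, so the fold changes were used only for direction and comparison. Log2 fold changes there and here correlated at r = 0.883 across the 18552 genes tested; genes are not independent replicates. That table covers 56262 genes, of which 861 have no TPM, 55401 have a TPM in every library and 25969 are listed at 0 in every library. Of the 861, 2 had an adjusted p under 0.05 in the authors' deposited table, Spry3 and an identifier without a symbol, and entered no test here. The 37 mitochondrially encoded genes are listed at 0 in all libraries, so a value of 0 is given here only as listed at 0. Per-sample columns that match no sample numbered 0.

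Symbols came from the authors' deposited table, where 409 genes had none and 1479 shared one with another identifier. Where a symbol was shared, the identifier with the highest mean TPM stands for it in the gene lists. A separate gene name table held 54349 of the identifiers with the same version. Positions came from a RefSeq table of GRCm38.p6, the assembly that mm10 names, which gave a position for 16209 of 18542 tested symbols (87.4%).

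Genes with a mean TPM of at least 0.5 over the 8 libraries were tested, 18552 in all, with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with group as the sole factor, a mean-variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale and understate the change of genes with low TPM. TPM keeps no read counts, so a count model was not used and depth per library is unknown from these values. An exact two-sided permutation test of 4 against 4 libraries cannot go below 0.0286. Experiment numbers are shared by both groups, and a fit with the number as a block was an alternative.

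Before the data were examined, 30 gene lists and 8 families defined by name were fixed, together with the rule for named genes: the 12 largest rises and falls among called genes with the same direction in all 4 experiment numbers, a mean of at least 10 TPM in the higher group and a symbol that is not a predicted name; any list member; and, per family, the largest rise, the largest fall and the 2 highest genes. The rule allows more genes than the text can hold, so 257 genes were followed, and the examples among them were chosen after their values were seen. The lists were naive pluripotency, formative and primed epiblast, neural progenitor, dorsoventral patterning, forebrain and midbrain, hindbrain and spinal cord, neuron, glia, neural crest and non-neural ectoderm, mesoderm, endoderm, mesenchyme and fibroblast, two-cell-like state, TRIM28 and H3K9me3 machinery, DNA methylation, Polycomb, imprinted, retrovirus-derived and host factor, viral sensing and interferon, germline, Wnt targets, ERK targets, LIF and STAT3 targets, Notch, Hedgehog, retinoic acid, glycolysis, cholesterol biosynthesis, cell cycle and housekeeping genes. The families were Hox, clustered protocadherins, Zfp, cytosolic ribosomal proteins, histones (by a name pattern meant for replication-dependent genes, which also takes in the replication-independent H1f0), mitochondrially encoded genes, olfactory receptors and Zscan4. Of 675 listed symbols 668 were found. Lists with at least 5 members past the filter were tested with camera (limma) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 tested, beside camera with an estimated correlation and fry. Camera compares a list with all other genes; an estimated correlation widens its error where members vary together.

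On simulated data with 200 changed genes among 18552, the gene test recovered 17.9% of genes changed by 0.5 on the log2 scale, 55.2% of those changed by 1 and 89.4% of those changed by 2, where 180 further genes, the members of 6 simulated lists, also moved by 1. Of all 196 calls in that simulation 191 were of changed genes with the right sign and 5 were false (2.55%). Of 6 simulated lists that moved 6 were called, and of 14 that did not 0 were. Simulated errors were independent between genes, while the estimated correlation within the real lists had a median of 0.231 and reached 0.951. The list result therefore does not carry over to lists whose members vary together. In the simulation 380 genes changed, against 9333 called in the data, so its shares recovered hold for that setting only. There, small changes were often missed with 4 libraries per group.

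Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, TMM recentring (30% of log ratios and 5% of levels trimmed at each end), quantile normalization, the replicate block, no trend, a robust fit, a 2-fold limit, and each library left out in turn. After seeing the data, fits without the ESC libraries of experiments 1 and 2, without those of experiments 3 and 4, and without the NPC libraries of experiments 2 and 3 were added, and the followed genes were also taken through TMM, both filters, no trend and the robust fit. Libraries standing apart in a group of 4 were found with Dixon's ratio at its 95% critical value, over the list means, the library measures and the 257 genes followed. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.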

Results

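Gene expression was measured by RNA sequencing in mouse embryonic stem cells (ESCs) and in neural progenitor cells (NPCs) made from them over 5 days of differentiation. The line, 46C, carries a GFP reporter in Sox1, a transcription factor gene used as a marker of neural progenitors. Each group had 4 libraries, numbered by experiment from 1 to 4. No label says that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The series concerns endogenous retroviruses that escape repression by TRIM28, a corepressor that brings histone H3K9 methylation to retroviral sequences. Only the gene-level RNA values were analysed here; the 12 CUT&RUN samples and the retroviral repeats themselves were not analysed here. TPM values (transcripts scaled to a fixed total) sum to 1000000 in every library, so they keep no depth and the depth per library is unknown from them. At least 1 TPM was reached by 15379.5 ± 376 genes in ESCs (SD, n = 4; 15017 to 15906) and 15855.5 ± 277 in NPCs (SD, n = 4; 15467 to 16113).

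The comparison of NPCs with ESCs asked which genes differed between pluripotent cells and their neural derivatives. At camera's preset correlation the naive pluripotency list was called lower and the neural progenitor and dorsoventral patterning lists higher, while no list passed with an estimated correlation (lowest adjusted p = 0.335). Tdh, the threonine dehydrogenase on which mouse ESCs depend, fell from 935 ± 67.3 TPM in ESCs to 1.93 ± 2.23 in NPCs (SD, n = 4 each). Crabp1, a retinoic acid binding protein gene, rose from 24.4 ± 12.9 to 5281 ± 954 TPM. Of 18552 genes tested with limma, 9333 were called at an adjusted p under 0.05, of which 6048 were higher and 3285 lower in NPCs. At least 2-fold on the log2(TPM + 1) scale were 3338 of the higher and 1880 of the lower genes, 5218 in all. Of the called genes, 8993 (96.4%) had the same direction in all 4 experiment numbers. The call itself favours such agreement, and groups that do not overlap give it under any numbering. The values of the 2 groups did not overlap for 8873 of the genes tested (47.8%), where chance gives 2.86%.

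The share of called genes that were higher depended on scaling. It was 64.8% with TPM as deposited and 49.4% (4616 higher, 4723 lower) after recentring on trimmed means (TMM), which moved the median log2 change of all genes by -0.21 from 0.16. The share was 52.1% (4817 higher, 4424 lower) after quantile normalization, which moved that median by -0.18. In the authors' deposited table, 48.2% of the 11897 tested genes with an adjusted p under 0.05 were higher (5736 higher, 6161 lower). That table and the test here shared 8582 calls, 92.0% of the calls made here, all with the same direction, while 751 were called here only and 3315 by the authors only. Statements on the balance of rises and falls, and small changes of single genes, therefore rest on the scaling. No gene called under TPM as deposited turned direction while called under either scaling.

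Named genes follow a rule fixed before the data were examined: the 12 largest rises and 12 largest falls, members of the fixed lists, and the extremes of the fixed gene families. From the genes this rule allows and those singled out later, 257 were followed through the alternatives, and the examples named were chosen from these after their values were seen. Of the 257, limma called 207, 206 of them with the same direction in all 4 experiment numbers, with adjusted p values of at most 0.0460. For the 12 largest rises and 12 largest falls the rule required that agreement. Of these 207, 14 lost their call when 1 of the 8 libraries was left out, and the closing section names them. Log2 changes are given ± SE with 4 libraries per group, and levels as mean TPM ± SD. Because the pseudocount of 1 pulls low values together, these log2 changes understate the change of genes with low TPM.

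Of the genes that met the rule, Crabp1 had the largest rise (log2 change 7.83 ± 0.34). Thbs1, encoding the matrix glycoprotein thrombospondin, rose by 7.57 ± 0.19 and reached 223 ± 51.0 TPM. Ptn, a growth factor gene of the developing nervous system, rose by 7.38 ± 0.41 to 311 ± 122 TPM. Ednrb, an endothelin receptor gene used by neural crest and glial precursors, rose by 6.64 ± 0.36, and Acta2, a smooth muscle actin gene, by 6.82 ± 0.21. Insl6, a relaxin family hormone gene, rose by 7.21 ± 0.47 to 564 ± 259 TPM. The Notch effector Hes5 rose by 7.01 ± 0.31, and the homeobox gene Irx3 by 6.86 ± 0.27. The imprinted genes Nnat and H19 rose by 7.38 ± 0.30 and 7.16 ± 0.33. The serine protease gene Prss23 and its opposite strand transcript Prss23os rose by 6.91 ± 0.14 and 7.55 ± 0.14; how the authors' counting used strand is not given in the sources used here, so the values of the pair are uncertain. On the GRCm38 (mm10) assembly Crabp1 lies on chromosome 9 at 54764748 to 54773110, Hes5 on chromosome 4 at 154960626 to 154962372, Nnat on chromosome 2 at 157560078 to 157562525 and Prss23 on chromosome 7 at 89507783 to 89527187.

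Among genes that met the rule the largest fall was of Tdh. This gene, on chromosome 14 at 63492347 to 63509092 (GRCm38), fell by 8.61 ± 0.43 (SE) on the log2(TPM + 1) scale. Dppa5a, encoding an RNA-binding protein of pluripotent cells, fell from 7043 ± 845 to 54.7 ± 48.2 TPM (log2 change -7.76 ± 0.85). Lefty2, a Nodal inhibitor gene, had a log2 change of -7.22 ± 0.54, and Notum, encoding a Wnt deacylase, of -6.49 ± 0.31. The pluripotency regulators Esrrb, Nr0b1, Zfp42 and Klf2 had log2 changes of -6.89 ± 0.55, -6.73 ± 0.33, -6.73 ± 0.67 and -6.44 ± 0.46, and the AKT coactivator gene Tcl1 had -6.85 ± 0.47. Fam25c changed by -6.61 ± 0.45 and the secreted phosphoprotein gene Spp1 by -6.28 ± 0.58. Rpl10l, a retrogene of Rpl10, changed by -6.83 ± 0.65, a value that is uncertain because reads can be shared with its near-identical parent.

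**Figure D1:**
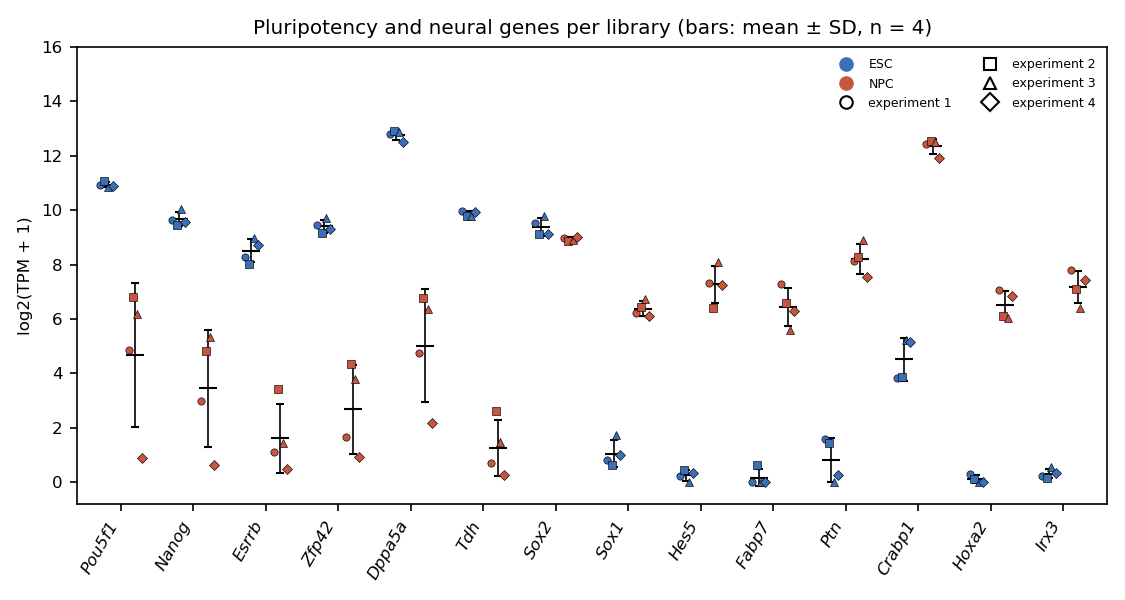
Log2(TPM + 1) of 14 named genes in each of the 8 libraries, with ESC libraries in blue and NPC libraries in red, symbols for the experiment numbers, and bars for the mean ± SD of 4 libraries. Pou5f1, Nanog and Dppa5a varied widely among the NPC libraries, Pou5f1 from 0.859 to 112 TPM, while Sox2 was at 680 ± 153 TPM in ESCs and 488 ± 22.3 in NPCs (SD, n = 4).

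Naive pluripotency genes fell. Of 25 list members tested, 24 fell, 1 rose and 0 were not called, with the same counts adjusted over the list alone. Pou5f1, which encodes OCT4, fell from 1959 ± 125 to 52.8 ± 48.7 TPM (log2 change -6.25 ± 1.08), Nanog from 830 ± 157 to 18.6 ± 18.1 TPM (-6.24 ± 0.87) and Tfcp2l1 from 189 ± 97.3 to 1.77 ± 1.90 TPM (-6.15 ± 0.48). The smallest fall was of Sall4, by 0.89 ± 0.18. Gbx2, a homeobox gene of the anterior hindbrain that is also a LIF target in ESCs, was the exception and rose by 1.74 ± 0.44. The list median was -5.63 and camera called the list lower (adjusted p = 1.42e-14), while adjusted p = 0.335 with an estimated correlation. The NPC libraries differed in what remained: Pou5f1 stood at 27.8, 112, 70.8 and 0.859 TPM, and Nanog at 6.97, 27.1, 39.7 and 0.539, in experiments 1 to 4.

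Neural progenitor genes rose. In this list 22 of 25 members rose, 1 fell and 2 were not called (23 and 1 adjusted over the list alone). Sox1 rose from 1.16 ± 0.812 to 83.3 ± 17.0 TPM (5.33 ± 0.26), its relative Sox3 from 11.5 ± 8.30 to 479 ± 85.0 TPM (5.54 ± 0.46), and Nes, encoding the progenitor intermediate filament nestin, from 18.0 ± 5.44 to 224 ± 76.5 TPM (3.54 ± 0.28). Fabp7, a fatty acid binding protein gene of radial glia, rose by 6.29 ± 0.34, the nuclear receptor gene Nr2f1 by 6.44 ± 0.31, and the N-cadherin gene Cdh2 by 5.21 ± 0.36. Sox2, which both pluripotent and neural progenitor cells use, was at 680 ± 153 TPM in ESCs and 488 ± 22.3 in NPCs (-0.45 ± 0.15, limma adjusted p = 0.0285). Its call was lost without the ESC library of experiment 1 (-0.41, adjusted p = 0.0676) and without the NPC library of experiment 1, 2 or 3 (-0.46, -0.43 and -0.44, adjusted p = 0.0566, 0.0676 and 0.0635), with no filter (adjusted p = 0.0507) and without the trend (adjusted p = 0.0538). Camera called the list higher (median 3.85, adjusted p = 4.59e-08), with adjusted p = 0.335 with an estimated correlation.

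Genes that pattern the dorsoventral axis of the neural tube rose as well, 14 of 16 tested members, with 0 lower and 2 not called, and the same counts adjusted over the list alone. Irx5 rose by 5.75 ± 0.21 to 65.4 ± 17.0 TPM, the dorsal and alar genes Pax7 and Pax3 by 3.66 ± 0.39 and 3.38 ± 0.36, and the ventral gene Nkx6-1 by 3.21 ± 0.40. Dbx1, a gene of intermediate neural tube progenitors, was listed at 0 in all ESC libraries and at 66.4, 10.1, 8.14 and 81.5 TPM in the NPC libraries of experiments 1 to 4. Shh, the ventral midline signal, was listed at 0 in all ESC libraries and at 3.23, 2.90, 4.17 and 4.83 TPM in NPC libraries. Camera called this list higher (median 2.38, adjusted p = 3.02e-05), and adjusted p = 0.335 with an estimated correlation.

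Along the head to tail axis none of the 3 lists was called with all libraries, while single genes, picked after their values were seen, changed. Hoxa2 rose to 94.5 ± 33.2 TPM (6.40 ± 0.25), Hoxb2 to 54.9 ± 18.5 TPM (5.69 ± 0.24) and Hoxb3 to 20.5 ± 11.7 TPM (4.12 ± 0.48). Cdx1, a caudal homeobox gene and Wnt target, fell by 4.74 ± 0.37. Of 18 hindbrain and spinal cord members 11 rose, 1 fell and 6 were not called, with the same counts adjusted over the list alone. The list as a whole missed the threshold (median 1.57, adjusted p = 0.0778; adjusted p = 0.792 with an estimated correlation), and passed it without the NPC library of experiment 4 (adjusted p = 0.00658), after TMM (0.0143) and after quantile normalization (0.0203). Of 20 Hox genes tested 8 rose, 2 fell and 10 were not called (8 and 2 adjusted over the list alone; median 0.51, adjusted p = 0.787), and its sign was not stable. The median of the Hox family was 0.43 after TMM and 0.38 after quantile normalization, but -0.14 with no filter, -0.01 without the NPC library of experiment 2, -0.00 without that of experiment 3, -0.75 without both and -0.14 without the ESC libraries of experiments 1 and 2. Of 9 forebrain and midbrain members 6 rose, 1 fell and 2 were not called (6 and 3 adjusted over the list alone; median 1.02, adjusted p = 0.618). Among them Otx2, a gene of the anterior brain and of epiblast cells, fell from 11.1 ± 6.92 to 1.56 ± 1.04 TPM (-2.11 ± 0.46).

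Genes of young neurons rose in 20 of 28 tested members, with 0 lower and 8 not called, and the same counts adjusted over the list alone. Elavl4, a neuronal RNA-binding protein gene, rose by 2.54 ± 0.35 to 11.4 ± 5.49 TPM, and the early neuronal gene Nhlh1 by 2.92 ± 0.57, with 17.5, 3.19, 4.09 and 22.9 TPM in the NPC libraries of experiments 1 to 4. Tubb3, the neuronal tubulin gene, was at 111 ± 13.8 TPM in ESCs and 140 ± 61.6 in NPCs and did not pass the test (0.23 ± 0.28). Camera called the neuron list higher (median 1.42, adjusted p = 0.000757), adjusted p = 0.660 with an estimated correlation, and the call was lost with only genes of at least 5 TPM (median 2.54, adjusted p = 0.114).

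Notch pathway genes rose in 16 of 17 tested members and 1 was not called, with the same counts adjusted over the list alone. The ligand gene Dll1 rose from 1.68 ± 1.38 to 60.8 ± 18.1 TPM (4.64 ± 0.38), the glycosyltransferase gene Lfng from 1.84 ± 0.919 to 77.2 ± 24.1 TPM (4.79 ± 0.30), and the feedback regulator Nrarp from 6.13 ± 1.20 to 94.9 ± 34.1 TPM (3.69 ± 0.26). Rbpj, the DNA-binding partner of Notch, did not pass the test, at 37.2 ± 4.53 and 34.9 ± 4.80 TPM. Camera called the Notch list higher (median 1.62, adjusted p = 0.000205), and adjusted p = 0.335 with an estimated correlation.

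Retinoic acid pathway genes rose in 12 of 20 members, fell in 3 and were not called in 5, with the same counts adjusted over the list alone. Besides Crabp1, Crabp2 rose from 17.5 ± 15.3 to 1124 ± 216 TPM (6.36 ± 0.57), and Cyp26b1, which degrades retinoic acid, rose by 6.26 ± 0.51 to 104 ± 72.3 TPM. The homeobox genes Meis1 and Meis2 rose by 4.40 ± 0.17 and 3.65 ± 0.20. The falls were of the receptor genes Rarg (-1.47 ± 0.42) and Rara (-0.89 ± 0.22) and of Aldh1a2, the main synthesis enzyme of the embryo (-1.36 ± 0.27). By camera this list was higher (median 1.53, adjusted p = 0.0184), and adjusted p = 0.464 with an estimated correlation. Hedgehog pathway genes rose in 7 of 12 members, fell in 1 and were not called in 4 (the same counts adjusted over the list alone), and the list missed the threshold (median 1.35, adjusted p = 0.0612; 0.660 with an estimated correlation). Smo, the signal transducer, rose from 12.1 ± 4.73 to 149 ± 12.0 TPM (3.59 ± 0.24) and the coreceptor genes Gas1 and Boc by 3.92 ± 0.18 and 4.42 ± 0.42. The Hedgehog list passed after TMM (adjusted p = 0.0263), after quantile normalization (0.0392), and without the ESC library of experiment 1 (0.0372) or 3 (0.0469) or the NPC library of experiment 4 (0.0434), with no filter (0.0108) and without the ESC libraries of experiments 1 and 2 (0.0470).

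Imprinted genes rose in 24 of 42 tested members, fell in 1 and were not called in 17 (24 and 2 adjusted over the list alone). Besides Nnat and H19, Mest, a paternally expressed hydrolase gene, rose from 111 ± 75.9 to 2932 ± 304 TPM (5.02 ± 0.48), the cell cycle inhibitor gene Cdkn1c from 14.5 ± 15.5 to 283 ± 131 TPM (4.75 ± 0.73) and the adaptor gene Grb10 from 12.7 ± 1.51 to 95.2 ± 5.85 TPM (2.82 ± 0.11). Gnas, encoding a stimulatory G protein subunit, rose by 3.09 ± 0.15. Igf2, a growth factor gene next to H19, rose by 3.57 ± 0.53, with 7.35, 43.8, 6.88 and 6.54 TPM in the NPC libraries of experiments 1 to 4. The transporter gene Slc22a18 was the member that fell (-1.63 ± 0.45). By camera imprinted genes were higher as a list (median 0.82, adjusted p = 0.00228), and adjusted p = 0.464 with an estimated correlation.

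Mesenchyme and fibroblast genes rose in 9 of 11 tested members, with 1 lower and 1 not called, and the same counts adjusted over the list alone. Besides Acta2, the actin-binding protein gene Tagln rose from 2.77 ± 0.787 to 224 ± 96.1 TPM (5.83 ± 0.29), and the collagen genes Col1a1 and Col5a1 rose by 3.15 ± 0.32 and 2.45 ± 0.16. Fn1, the fibronectin gene, fell from 505 ± 198 to 124 ± 7.95 TPM (-1.95 ± 0.23). The list was called higher (median 2.45, adjusted p = 0.00719), and adjusted p = 0.335 with an estimated correlation. Of 14 neural crest and non-neural ectoderm members 7 rose, 5 fell and 2 were not called, with the same counts adjusted over the list alone. The keratin genes Krt8 and Krt18 rose by 3.22 ± 0.66 and 4.57 ± 0.32, and Cdh1, the epithelial cadherin gene, fell by 3.58 ± 0.37. That list was not called (adjusted p = 0.839), and its median of 0.89 and mean of 0.43 were above 0 while the test pointed lower; it pointed higher under TMM and quantile normalization.

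Markers of the remaining cell types gave no call as lists. Of 9 endoderm members 4 rose, 2 fell and 3 were not called (the same adjusted over the list alone; median 0.91, adjusted p = 0.262), among them Cxcr4, also a chemokine receptor gene of migrating neural cells (5.03 ± 0.22), and the basement membrane collagen gene Col4a1 (4.52 ± 0.33). The list passed without the ESC library of experiment 3 (adjusted p = 0.0398), without the ESC libraries of experiments 3 and 4 (0.0269) and with only genes of at least 5 TPM (0.0371). Of 10 mesoderm members 1 rose, 2 fell and 7 were not called (0 and 2 adjusted over the list alone), with a median of 0.27, a mean of -0.20 and a test pointing lower (adjusted p = 0.628). Of 11 glial members 5 rose, 3 fell and 3 were not called (6 and 3 adjusted over the list alone; median 0.87, adjusted p = 0.618); Fgfr3, a receptor gene of neural progenitors and astrocytes, rose by 6.20 ± 0.40 and the lipoprotein gene Apoe fell by 2.56 ± 0.27. Of 13 formative and primed epiblast members 4 rose, 2 fell and 7 were not called (4 and 1 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 0.618) and ran from -0.48 to 1.60 across settings. That list passed without the ESC libraries of experiments 1 and 2 (median 1.60, adjusted p = 0.0328). Members that rose included Sox4 (5.09 ± 0.22) and Sall2 (4.47 ± 0.14), which neural cells also use. Two-cell-like genes gave 0 calls in 11 members with limma, also adjusted over the list alone (median 0.15, mean 0.00 and test pointing lower, adjusted p = 0.628), and the 9 Zscan4 cluster genes gave 0 (median 0.15 and mean 0.13 with the test pointing lower, adjusted p = 0.787). The median of the two-cell-like list was -0.02 after TMM and -0.08 after quantile normalization, and that of the Zscan4 cluster was 0.00 and -0.08. Across all settings the 2 medians were less stable, from -1.01 to 0.50 for the two-cell-like list and from -0.89 to 0.94 for the Zscan4 cluster.

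Targets of LIF and STAT3, the signalling route that sustains naive ESCs, were lower in NPCs in 6 of 15 members and higher in 1, with 8 not called and the same counts adjusted over the list alone. Jak3, a kinase gene, fell from 72.4 ± 57.7 to 5.92 ± 1.89 TPM (-3.04 ± 0.56), and Klf4 and Klf5 fell by 4.19 ± 0.64 and 4.57 ± 0.50; Klf4, Klf5, Tfcp2l1 and Gbx2 are also on the naive list. Socs3, the feedback inhibitor gene of the pathway, did not pass the test, with 0.148, 1.55, 108 and 52.6 TPM in the ESC libraries of experiments 1 to 4 and 19.2 ± 4.97 TPM in NPCs. Stat3 did not pass either, with 9.08, 7.20, 56.9 and 54.8 TPM in ESC libraries and 7.95 ± 1.34 in NPCs; it passed without the ESC library of experiment 1 (-1.75, adjusted p = 0.0479) or 2 (-1.85, adjusted p = 0.0262) and after quantile normalization (-1.66, adjusted p = 0.0458). Without the ESC libraries of experiments 1 and 2, chosen after seeing the data, Socs3 was lower in NPCs (-1.95), and without those of experiments 3 and 4 it was higher (3.53). Camera called the LIF list lower (median -0.91, adjusted p = 0.00298; adjusted p = 0.715 with an estimated correlation), and the call was lost without the ESC libraries of experiments 3 and 4 (adjusted p = 0.0581).

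**Figure D2:**
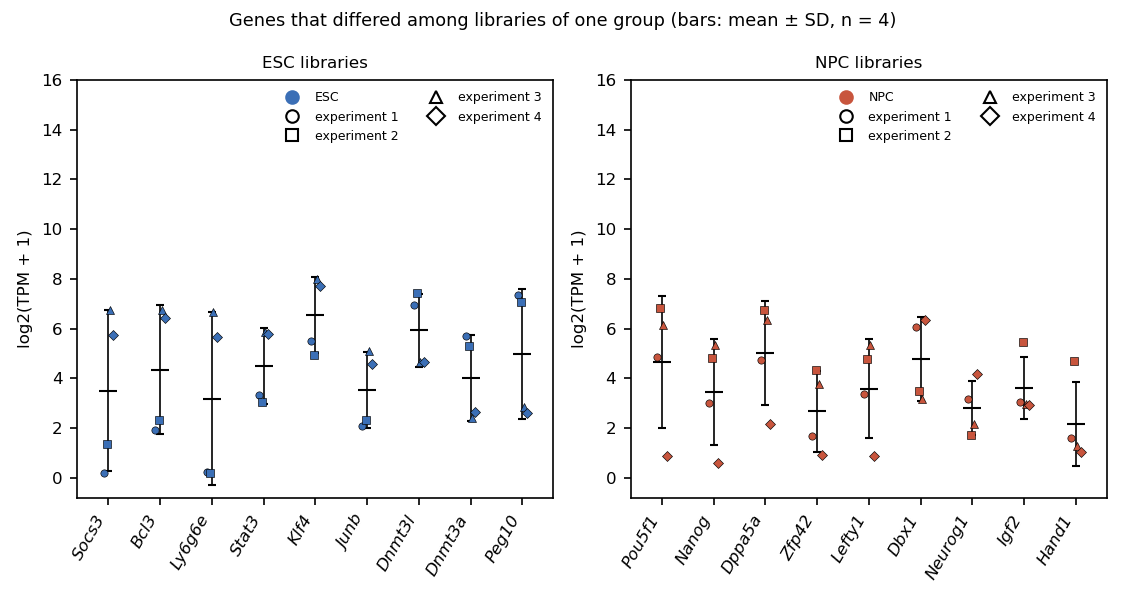
Log2(TPM + 1) of genes that differed among the 4 ESC libraries (left, blue) and among the 4 NPC libraries (right, red), with symbols for the experiment numbers and bars for the mean ± SD; the genes were chosen after their values were seen. Socs3 ranged from 0.148 to 108 TPM among ESC libraries, and Pou5f1 from 0.859 to 112 TPM among NPC libraries.

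Of the genes for TRIM28 repression and H3K9 methylation, 13 of 39 tested members rose, 14 fell and 12 were not called (13 and 15 adjusted over the list alone). Trim28 itself fell from 1265 ± 159 to 779 ± 81.2 TPM (-0.70 ± 0.12). The H3K9 methyltransferase gene Setdb1 fell from 79.2 ± 5.60 to 57.7 ± 4.97 TPM (-0.45 ± 0.10), and the HUSH complex gene Tasor by 1.67 ± 0.22. Zinc finger members of the list, picked after their values were seen, went both ways. Zfp57, which protects imprints, fell from 244 ± 49.1 to 53.1 ± 4.03 TPM (-2.16 ± 0.14), and Zfp809, which binds a retroviral primer site, Zfp819 and Rex2 had log2 changes of -1.31 ± 0.27, -3.88 ± 0.30 and -3.94 ± 0.19. Zfp445, which also protects imprints, rose (0.42 ± 0.14). Its call was lost after TMM (0.18), after quantile normalization (0.28), and without the ESC library of experiment 1 (0.43), 2 (0.33) or 4 (0.40) or the NPC library of experiment 1 (0.41), 2 (0.39) or 3 (0.38). Zfp568 (-0.49 ± 0.22) and Zfp932 (0.04 ± 0.15) were not called. Zfp568 was lower after TMM (-0.74), after quantile normalization (-0.61) and without the NPC library of experiment 2 (-0.69), and Zfp932 had the opposite sign after TMM (-0.19) and quantile normalization (-0.25). Suv39h1 and Ehmt1, 2 other H3K9 methyltransferase genes, rose by 1.58 ± 0.10 and 1.43 ± 0.10, and the HUSH gene Pphln1 by 1.95 ± 0.14. The list missed the threshold (median -0.18, adjusted p = 0.0612; 0.791 with an estimated correlation). After TMM 6 members were higher and 19 lower and the list passed (adjusted p = 0.0222), after quantile normalization 10 were higher and 18 lower (adjusted p = 0.0907), and it passed without the ESC library of experiment 3 (0.0469) or the NPC library of experiment 2 (0.0466), without the ESC libraries of experiments 3 and 4 (0.0473) and without the NPC libraries of experiments 2 and 3 (0.0295). Genes named Zfp, many of which encode zinc finger repressors, rose in 138 and fell in 59 of 363, with 166 not called (139 and 60 adjusted over the list alone; median 0.25, adjusted p = 0.538); the split was 109 to 94 after TMM and 102 to 98 after quantile normalization. Besides Zfp42, the family's rule named Zfp503, a developmental brain gene (5.74 ± 0.29), and Zfp428 (-1.45 ± 0.28).

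Retrovirus-derived genes and host factors rose in 10 of 24 members, fell in 4 and were not called in 10, with the same counts adjusted over the list alone (median 0.20, camera adjusted p = 0.839). After TMM 7 rose and 6 fell (median 0.03), and after quantile normalization 8 rose and 4 fell (median 0.01). Peg10, an imprinted gene derived from a retrotransposon, rose by 4.51 ± 1.07 to 739 ± 224 TPM, from 164, 136, 6.17 and 5.12 TPM in the ESC libraries of experiments 1 to 4; the log2 change was 2.26 without the ESC libraries of experiments 3 and 4. The related genes Rtl6 and Rtl5 rose by 2.57 ± 0.19 and 2.36 ± 0.26. Mov10, an RNA helicase gene, fell from 166 ± 42.7 to 9.84 ± 1.70 TPM (-3.93 ± 0.19), and Apobec3, a cytidine deaminase gene, from 19.2 ± 2.90 to 2.45 ± 0.473 TPM (-2.55 ± 0.17); each acts against retroelements. Viral nucleic acid sensing and interferon genes fell in 8 of 22 members, rose in 5 and were not called in 9 (9 and 5 adjusted over the list alone). Ifitm1, an antiviral membrane protein gene, fell from 488 ± 165 to 45.7 ± 21.0 TPM (-3.46 ± 0.35), the RNA sensor gene Ddx58 had a log2 change of -2.81 ± 0.21 and Oas1a, encoding an RNA-activated synthetase, of -4.43 ± 0.40. The antigen presentation genes B2m and H2-D1 rose by 2.37 ± 0.41 and 2.08 ± 0.23, opposite to the list. The list was called lower (median -0.42, adjusted p = 0.0422; adjusted p = 0.791 with an estimated correlation). That call was lost without the ESC library of experiment 3 (median -0.19, adjusted p = 0.0787) or 4 (-0.27, 0.0707), without the NPC library of experiment 1 (-0.37, 0.0584) or 2 (-0.43, 0.0522), after TMM (-0.65, 0.0808), with no filter (-0.10, 0.122), with the experiment number as a block (-0.42, 0.0591) and without the ESC libraries of experiments 3 and 4 (0.16, 0.407), and the median was -0.66 without the ESC library of experiment 2.

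DNA methylation genes rose in 6 of 18 members, fell in 6 and were not called in 6 (7 and 7 adjusted over the list alone); the median was 0.17, the mean -0.42 and the test pointed lower (adjusted p = 0.628), and the median was -0.08 after TMM. The dioxygenase genes Tet1 and Tet2 fell by 2.57 ± 0.19 and 1.95 ± 0.33, and Tet3 rose from 1.84 ± 0.551 to 20.9 ± 3.29 TPM (2.96 ± 0.20). Dnmt3a, a de novo methyltransferase gene, did not pass the test, with 51.3, 39.1, 4.31 and 5.21 TPM in the ESC libraries of experiments 1 to 4 and 20.0 ± 1.26 TPM in NPCs. Polycomb genes rose in 11 of 34 members, fell in 12 and were not called in 11 (12 and 12 adjusted over the list alone), with a median of 0.15, a mean of 0.15 and a test that pointed lower (adjusted p = 0.651); the median was -0.10 after TMM and -0.02 after quantile normalization. Of the PRC2 complex, which methylates H3K27, Suz12 fell from 200 ± 21.1 to 68.1 ± 11.8 TPM (-1.55 ± 0.14) and Eed by 1.03 ± 0.11, while Ezh2, its catalytic subunit gene, rose from 69.5 ± 2.73 to 128 ± 6.65 TPM (0.87 ± 0.08). Of the PRC1 complex Cbx7 fell by 1.49 ± 0.39 and Phc1 by 1.19 ± 0.21, while Cbx2 rose by 2.24 ± 0.11 and Phc2 by 2.76 ± 0.11. Each of these Polycomb genes kept its direction and call after TMM and quantile normalization.

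Germline genes fell in 11 of 22 members, rose in 1 and were not called in 10, with the same counts adjusted over the list alone. Dazl, a germ cell RNA-binding protein gene, fell by 3.39 ± 0.47, and the meiotic genes Hormad1 and Hsf2bp had log2 changes of -3.71 ± 0.27 and -4.06 ± 0.31. Tdrkh, a piRNA pathway gene, rose from 0.656 ± 0.396 to 23.0 ± 5.63 TPM (3.86 ± 0.24). Camera called the germline list lower (median -1.29, adjusted p = 0.000167), and adjusted p = 0.464 with an estimated correlation. Clustered protocadherin genes, which give neurons their surface identity, rose in 14 of 22 members, fell in 1 and were not called in 7 (15 and 1 adjusted over the list alone). Pcdhgc3 rose from 12.9 ± 2.02 to 71.9 ± 7.42 TPM (2.40 ± 0.13). Genes of its gamma cluster share 3' exons, so the values of these members are uncertain. The family was called higher (median 0.99, adjusted p = 0.0106), and adjusted p = 0.660 with an estimated correlation.

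Cytosolic ribosomal protein genes were lower by a small amount. Of 75, 42 fell, 0 rose and 33 were not called with limma (47 and 0 adjusted over the list alone), with a median of -0.32. After TMM 67 fell and 0 rose, and after quantile normalization 13 fell, 2 rose and the median was -0.14. Rps12 fell from 2689 ± 246 to 1625 ± 195 TPM (-0.73 ± 0.11). The share of all TPM taken by this family was 15.5 ± 1.53% in ESCs and 12.4 ± 0.733% in NPCs (SD, n = 4). The family was called lower (adjusted p = 5.73e-09), and adjusted p = 0.715 with an estimated correlation. Glycolysis genes fell in 6 of 22 members, rose in 1 and were not called in 15, with the same counts adjusted over the list alone; the list was called lower (median -0.28, adjusted p = 0.0354; adjusted p = 0.715 with an estimated correlation). Ldhb, a lactate dehydrogenase gene, fell from 1060 ± 138 to 67.9 ± 11.3 TPM (-3.95 ± 0.13) and the phosphofructokinase gene Pfkp by 3.30 ± 0.29. The glycolysis call was lost without the NPC library of experiment 1 (median -0.21, adjusted p = 0.0741) or 2 (-0.26, 0.102), after quantile normalization (-0.05, 0.290), without the ESC libraries of experiments 1 and 2 (-0.06, 0.0728) and without the NPC libraries of experiments 2 and 3 (-0.25, 0.118). Cholesterol biosynthesis genes rose in 15 of 22 members, fell in 1 and were not called in 6 (16 and 1 adjusted over the list alone), and the list missed the threshold (median 0.54, adjusted p = 0.0540; 0.791 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, rose by 1.62 ± 0.18 and Ebp, a late one, fell by 1.43 ± 0.26. The cholesterol list passed after quantile normalization (adjusted p = 0.0195), with a pseudocount of 5 (0.0335), with no filter (0.00579), without the ESC libraries of experiments 1 and 2 (0.0128) and without the ESC library of experiment 1 (0.0198) or the NPC library of experiment 1 (0.0347) or 4 (0.0331). After TMM 8 members rose and 3 fell, and this list did not pass (median 0.29, camera adjusted p = 0.0881).

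Cell cycle genes rose in 11 of 32 members, fell in 5 and were not called in 16, with the same counts adjusted over the list alone (median 0.11, camera adjusted p = 0.828). After TMM 6 rose and 9 fell (median -0.14), and after quantile normalization 9 rose and 7 fell (median 0.07). The cyclin gene Ccnd2 rose from 3.35 ± 3.80 to 216 ± 77.7 TPM (6.10 ± 0.68) and the proliferation marker Mki67 by 1.08 ± 0.12, while Trp53, encoding p53, fell by 1.07 ± 0.11. Wnt target genes fell in 6 of 16 members, rose in 3 and were not called in 7 (the same adjusted over the list alone; median -0.58, adjusted p = 0.180); Sp5 fell by 4.06 ± 0.43 and Sp8 rose by 3.66 ± 0.33. ERK targets rose in 7 of 20 members, fell in 3 and were not called in 10 (the same adjusted over the list alone; median 0.42, adjusted p = 0.828). Dusp5, an ERK phosphatase gene, rose by 3.68 ± 0.48 and the FGF-responsive factor Etv5 fell from 436 ± 51.3 to 30.5 ± 24.8 TPM (-4.09 ± 0.44). The treatment label names 2i for ESCs, while NPCs had been differentiated. Effects of medium and of cell state therefore cannot be told apart for the Wnt, ERK and LIF target lists. Of 53 histone genes of the family fixed by name, meant to hold replication-dependent ones, 7 rose, 0 fell and 46 were not called (3 and 0 adjusted over the list alone), with a median of 0.08, a mean of 0.22 and a test pointing lower (adjusted p = 0.899); the median was -0.07 after TMM and -0.15 after quantile normalization. The name pattern also took in H1f0, a replication-independent linker histone gene and 1 of the 7, which rose by 2.23 ± 0.17. Housekeeping genes rose in 4 of 20 members, fell in 6 and were not called in 10 (the same adjusted over the list alone; median -0.16, mean -0.04, adjusted p = 0.161), and after TMM 1 rose, 11 fell and the list passed (adjusted p = 0.0326). The actin gene Actb, at 2078 ± 408 and 1670 ± 290 TPM, did not pass (-0.31 ± 0.18), but was lower after TMM and without the ESC library of experiment 3 (-0.47, adjusted p = 0.0198). Hprt stayed under 3 TPM in all 8 libraries, from 0.200 to 2.89 TPM.

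In all, 38 lists and families had been fixed, 36 were tested and 14 were called with camera at its preset correlation, 8 higher and 6 lower; with an estimated correlation 0 passed, the lowest adjusted p being 0.335. At an unadjusted p under 0.05, 5 of the 36 passed with an estimated correlation. The directional test of fry, which asks only whether a list's own genes move on balance in a single direction, passed for 27 lists, among them all 14 called, and its test for change in either direction passed for 34. The mitochondrially encoded genes were listed at 0 in all libraries and were not tested, and of 1116 olfactory receptor genes 3 passed the filter, too few to test; Olfr985, of that family, fell by 2.08 ± 0.17.

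**Figure D3:**
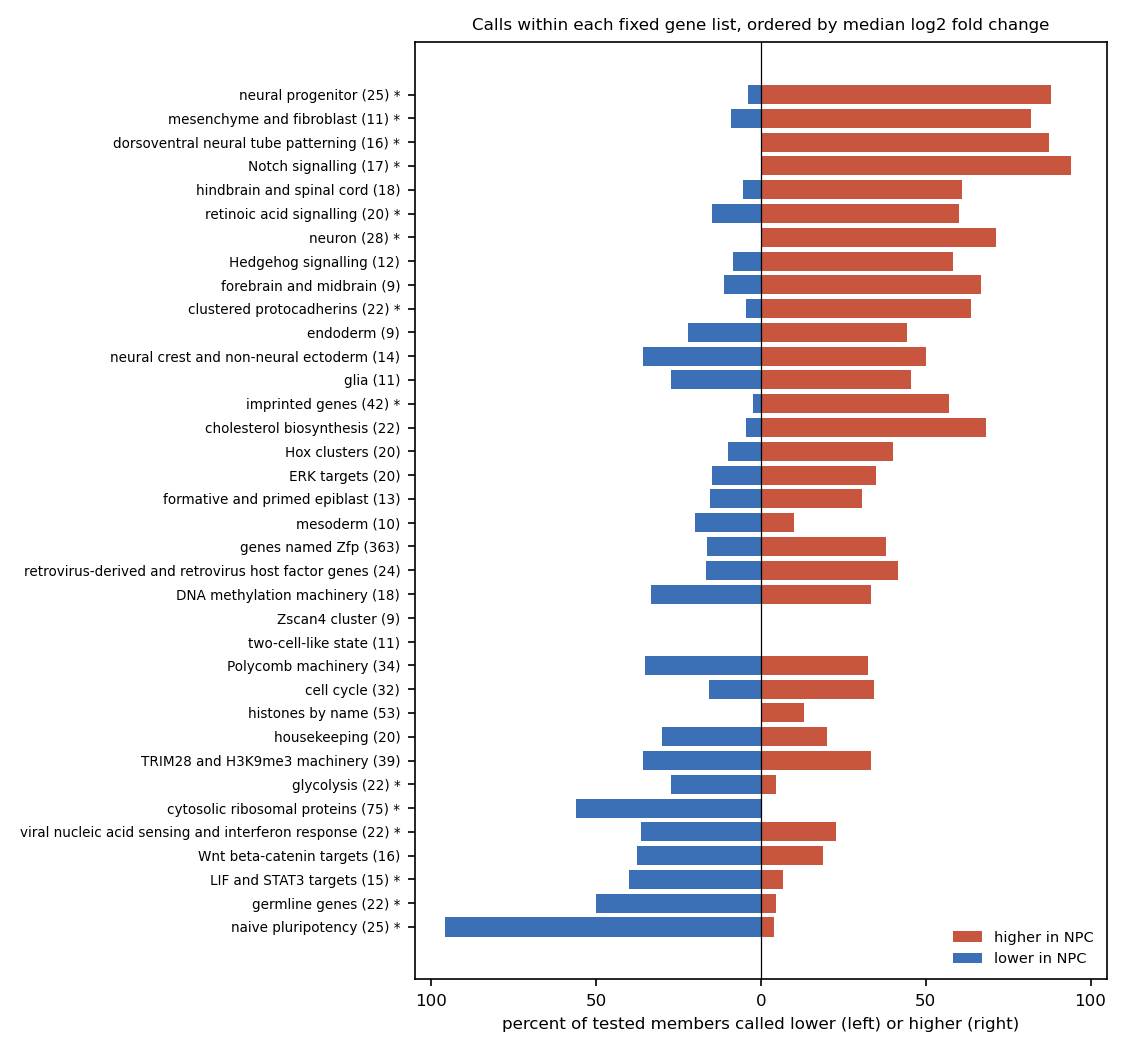
Percent of the tested members of each fixed list or family called lower (blue, left) or higher (red, right) in NPCs, with the number tested in brackets, an asterisk for lists called with camera at the preset correlation, and lists ordered by median log2 change. Naive pluripotency genes stand at the lower end with 24 of 25 members lower, and neural progenitor genes at the upper end with 22 of 25 higher; 2 of 75 ribosomal protein genes were higher after quantile normalization, where none was before.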

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

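The ratio that marks a library as standing apart was fixed beforehand, while the 257 genes it was run on were chosen partly after their values were seen. Of 478 groups of 4 libraries, over these genes, the list means and the library measures, 23 (4.81%) held a library past Dixon's 95% critical value, where chance gives about 5%. By library the 23 fell as 2, 1, 5 and 0 in the ESC libraries of experiments 1 to 4 and as 2, 5, 6 and 2 in the NPC libraries. No explanation was weighed for them, except that unchanged ESCs were set against Hand1 in the NPC library of experiment 2 under the other observations.

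The NPC library of experiment 2 stood apart with the highest Igf2 (43.8 TPM), Hand1, a mesoderm and trophoblast gene (25.1 TPM), and Zfp978 (6.10 TPM), and with the lowest Sall2 (130.1 TPM) and Ncam1, a neural adhesion gene (13.3 TPM). Ncam1 was not called with all libraries, and was without the ESC library of experiment 3 (0.72) and without those of experiments 3 and 4 (0.90). The NPC library of experiment 3 had the highest Stra6, a retinol receptor gene (34.2 TPM), ribosomal protein gene Rplp1 (10128 TPM) and Gusb, a housekeeping enzyme gene (29.9 TPM), and the lowest Fbn1, encoding fibrillin (10.2 TPM), Col5a1 (30.1 TPM) and Zfp428 (81.3 TPM). The call of Rplp1 was lost without the NPC library of experiment 1 (-0.37) or the ESC library of experiment 4 (-0.35), and that of Gusb without the ESC library of experiment 1 (0.67) or 2 (0.71) or the NPC library of experiment 1 (0.87) or 3 (0.75). The NPC library of experiment 1 had the highest Sox21, a neural progenitor gene (230 TPM), and the lowest Col4a1 (54.9 TPM). That of experiment 4 had the highest Gapdh (4722 TPM), which was not called with all libraries (-0.27), was lower without this library (-0.38) and after TMM (-0.52), and changed by 0.03 after quantile normalization, and the lowest share of TPM in small noncoding genes (0.334%).

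In ESCs the library of experiment 3 had the highest Ldhb (1265 TPM), H1f0 (104 TPM) and antigen presentation gene H2-K1 (21.3 TPM), the lowest Actb (1469 TPM), which was called lower without it (-0.47), and the highest mean log2(TPM + 1) over germline genes (3.20). The ESC library of experiment 2 had the lowest Bmi1, a Polycomb gene (17.7 TPM). That of experiment 1 had the highest mean over TRIM28 and H3K9me3 genes (5.94) and the lowest over hindbrain and spinal cord genes (0.89).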

How the results depend on the processing

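The fits without 2 libraries, and single genes under TMM, the filters, no trend and the robust fit, were chosen only after the results were seen; the other alternatives were fixed beforehand. The number of called genes, 9333, was between 6773 (filter of 5 TPM) and 9480 (no filter) in the other settings of pseudocount, filter, scaling, trend and block, and between 7974 (without the NPC library of experiment 1) and 9009 (without the ESC library of experiment 3) with 1 library left out. A 2-fold limit left 5218 genes, 3338 higher and 1880 lower, fewer by its construction. Without the ESC libraries of experiments 1 and 2, without those of experiments 3 and 4, and without the NPC libraries of experiments 2 and 3, 9142, 8551 and 7568 genes were called. No gene called with all libraries was called in the opposite direction in another setting, and the lowest share of calls kept was 77.8%, without those NPC libraries. The median of all genes moved by -0.11 with no filter. With the experiment number as a block, 8686 genes (5606 higher, 3080 lower) and 13 lists were called. Of the genes called without the block, 8473 (90.8%) kept their call. The numbers did not pair the samples: same-numbered libraries deviated from their group means with correlations between -0.0092 and 0.0425 across genes, and 2 of 4 ESC and 1 of 4 NPC libraries correlated best with their own number, a hint from the data and not the design. The block ended the calls of the viral sensing list (adjusted p = 0.0591, where all settings gave 0.0128 to 0.407), Axin2 (adjusted p = 0.0508) and Pcdhga11 (adjusted p = 0.0554). From 13 to 17 lists were called across settings. Naive pluripotency, neural progenitor, dorsoventral, Notch, imprinted, mesenchyme, retinoic acid, germline and ribosomal protein lists were called in 18 of 18 settings and protocadherins in 17 of 17 that could test them. The LIF list was called in 17, neuron in 17, glycolysis in 13 and viral sensing in 10 of 18. Among lists not called in the first place, cholesterol biosynthesis passed in 7 settings, Hedgehog in 7, TRIM28 in 5, hindbrain in 3, endoderm in 3, and housekeeping and epiblast in 1 each. Some lists and families could not be tested with a filter of 5 TPM, which left 31 of them. Of 22 lists not called, 10 had medians on both sides of 0 across settings, and of the 14 called 1 did, viral sensing. Of the 207 called genes among the 257 followed, 14 lost their call with 1 library left out, 25 with 2 left out and 15 in the other settings; of the 50 not called, 22, 28 and 14 gained one. TMM ended 6 calls (Cbx5, Gusb, Slc2a1, Spred1, Vcp, Zfp445) and added 8, quantile normalization ended 5 and added 5, and no filter ended 5 (Crxos, Dnmt3l, Eef1a1, Rplp1, Sox2). The filter of 5 TPM removed 31 of the followed genes. Against the sign with all libraries, Socs3 (-1.95) and Junb (-0.95) were lower in NPCs without the ESC libraries of experiments 1 and 2, and Dnmt3a (-1.13) without those of experiments 3 and 4; the cause was not tested. Socs3 (3.53), Junb (1.66) and Dnmt3a (1.87) were called higher in the other of these fits. Eef1a1 and Rplp1, among the most abundant genes, had log2 changes of 2.53e-15 and -2.05e-15 after quantile normalization, which are 0 to rounding, so the opposite sign of Eef1a1 there carries no direction. The 14 were Axin2, lost without the ESC library of experiment 2 (-0.72) or 4 (-0.65) or the NPC library of experiment 1 (-0.77) or 4 (-0.63); Cbx5 (ESC 4, 0.53; NPC 2, 0.59); Crxos (-2.67 to -3.75, all but ESC 1 and ESC 2); Dnmt3l (ESC 1, -2.67; ESC 2, -2.51; NPC 1, -2.80; NPC 4, -2.23); Eef1a1 (-0.27 to -0.36, all but ESC 1 and NPC 3); Epcam (ESC 1, -1.22; ESC 2, -1.13; NPC 1, -1.02; NPC 4, -1.14); Gusb (ESC 1, 0.67; ESC 2, 0.71; NPC 1, 0.87; NPC 3, 0.75); Mavs (ESC 3, -0.59; ESC 4, -0.62; NPC 1, -0.66; NPC 3, -0.73); Pcdhga11 (ESC 1, 0.91; ESC 2, 0.82; NPC 1, 0.94; NPC 2, 0.89); Rplp1 (ESC 4, -0.35; NPC 1, -0.37); Slc2a1 (ESC 2, 0.56); Sox2 (ESC 1, -0.41; NPC 1, -0.46; NPC 2, -0.43; NPC 3, -0.44); Sst (NPC 1, 2.61); and Zfp445 (0.33 to 0.43, all but ESC 3 and NPC 4). With 2 libraries left out, among others, calls of Gbx2 (1.14), Rarg (-0.71) and Cbx7 (-1.34) were lost without the ESC libraries of experiments 1 and 2, that of Rara (-0.64) without those of experiments 3 and 4, and those of Peg10 (4.23), Slc22a18 (-1.57), Bcl3 (-4.17) and Gbx2 (1.19) without the NPC libraries of experiments 2 and 3; with 6 libraries the test has less power. Hprt lost its call after quantile normalization (0.68). TPM keeps no depth, so how far counting error limits genes of low TPM is unknown.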

Other observations

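The tests of the 3 patterns below and the counts over other splits of the samples were chosen only after the results were seen, and the genes singled out here were chosen after their values were seen.

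Zinc finger genes near an end of chromosome 4 fell together in NPCs, while Zfp genes elsewhere mostly rose or were not called. Between 145510759 and 147849126 on chromosome 4 (GRCm38), 14 of 15 tested genes named Zfp, Rex2 included, fell with limma, and Zfp933 did not pass (0.23 ± 0.20). Zinc finger genes under predicted or clone names were not counted. Zfp978 fell from 119 ± 38.2 to 1.75 ± 2.90 TPM (SD, n = 4; log2 change -5.87 ± 0.54), Zfp980 and Zfp981 had log2 changes of -4.87 ± 0.30 and -4.80 ± 0.39, and Zfp990 fell from 86.5 ± 12.7 to 5.49 ± 2.70 TPM (-3.84 ± 0.28). Near-identical copies lie in this stretch, so the value of any single member is uncertain. Outside it 138 of 349 Zfp genes rose and 46 fell, with a median of 0.32. The split of the whole family between rises and falls, 138 to 59, was 102 to 98 after quantile normalization.

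For this cluster, log2 changes were shuffled over the 360 located Zfp genes: a 3 Mb window with a mean as low as -3.05 appeared in a share of 0.00095 of 100000 permutations (one-sided). This argues against chance placement of genes that change independently, which near-identical copies that share reads may not do. The summed TPM of these Zfp genes and Rex2 was 668, 491, 568 and 466 in ESC libraries and 26.9, 55.3, 49.9 and 25.1 in NPC libraries. That is a log2 change of -3.88 (-3.07 to -4.74 over pairs of libraries). Reads moving only among these genes would have kept this sum. Zinc finger genes under predicted or clone names were left out of it, so reads moved to copies among them are not excluded. Library scaling was argued against by the 14 genes that were still lower after quantile normalization. The fall of the sum does not exclude that reads of a few falling copies were also counted for their neighbours. A shared biological control of the cluster may underlie the fall, as a hypothesis found on these data and not tested.

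The NPC libraries differed in what remained of ESC transcripts. Dppa5a stood at 26.0, 108, 81.7 and 3.51 TPM, Esrrb at 1.18, 9.65, 1.70 and 0.399, and Lefty1, a Nodal inhibitor gene, at 9.41, 26.5, 39.9 and 0.824 TPM in experiments 1 to 4. Summed over the Zscan4 cluster, whose genes mark a rare state of ESC cultures, the libraries had 6.71, 42.6, 61.8 and 0.696 TPM in NPCs and 43.3, 24.6, 3.92 and 9.04 TPM in ESCs. The proneural gene Neurog1 was at 8.04, 2.33, 3.45 and 17.2 TPM in NPCs. A few genes active in placenta or extraembryonic mesoderm, picked after their values were seen and not tested as a group, were highest in the NPC library of experiment 2: Hand1 was at 25.1 TPM against 2.07, 1.46 and 1.09 in experiments 1, 3 and 4, Esx1 at 58.8 TPM against 10.5, 2.71 and 1.22, and Rhox9 at 31.5 TPM against 6.47, 3.15 and 1.46.

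Unchanged ESCs left in an NPC culture may account for naive transcripts there, and would hold all abundant naive genes at a single percent of their ESC level. Over 14 genes with at least 100 TPM in ESCs and at most 1% of it in the NPC library of experiment 4, the level in that library was taken off and values at or under 0 were set to the lowest above it; the ratio of the 90th to the 10th percentile of these percents was then 8.96, 4.71 and 36.1 in the NPC libraries of experiments 1, 2 and 3 (6.17, 4.94 and 27.5 with nothing taken off), and at most 2.11 in an ESC library, with nothing taken off. The bootstrap interval over genes in experiment 3 (7.06 to 48.0, or 5.29 to 44.6 with nothing taken off) lies above 2 times that ESC ratio (4.22), which would argue against unchanged ESCs as the whole source there. However, the low end of the percents rests on genes near the floor, with Tcl1 listed at 0 and Nr0b1 at 0.371 TPM in that library. Counting error there is unknown and can widen the ratio, so the ratio alone does not settle it. In experiments 1 (3.55 to 12.6, or 2.42 to 26.9) and 2 (2.18 to 9.10, or 2.04 to 55.7) the interval does not lie above that bound. By this ratio the explanation cannot be told apart from a partial shutdown at this number of genes. The reading depends on the bound, chosen after the values were seen. Of the 14 genes, Dppa5a, Pou5f1, Nanog and Utf1 had the highest TPM in each of the NPC libraries of experiments 1 to 3. Dppa5a stood there at 0.369, 1.53 and 1.16% of its ESC level, and Utf1 at 2.73, 13.9 and 7.92%. Pou5f1 and Nanog lay between. Utf1 ran from 151 to 635 TPM among ESC libraries. For these genes, chosen after their values were seen, the percents argue against unchanged ESCs as the whole source. Unchanged ESCs would not supply Hand1, Esx1 and Rhox9 in experiment 2 or the Zscan4 sum in experiment 3. These lay above every ESC library (Esx1 at most 4.84, Rhox9 at most 4.23, the Zscan4 sum at most 43.3 TPM). In experiments 1 and 2 the Zscan4 sums were 6.71 and 42.6 TPM, while naive genes stood at medians of 0.546 and 3.01% of their ESC level. Unchanged ESCs at such shares would not supply these sums either. No biological explanation was tested.

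The ESC libraries differed in LIF and STAT3 target genes. Bcl3 stood at 2.76, 3.97, 107 and 86.4 TPM, Ly6g6e at 0.168, 0.135, 102 and 50.5, and Junb at 3.30, 4.10, 33.0 and 23.0 TPM in the ESC libraries of experiments 1 to 4. Other genes ran the opposite way: Dnmt3l, a cofactor of de novo DNA methylation, stood at 124, 171, 24.5 and 24.5 TPM, and Fgf8 at 10.3, 7.79, 0.191 and 0.268. Dnmt3l was called lower in NPCs (-3.01, limma adjusted p = 0.0320), a call lost without the ESC library of experiment 1 (-2.67) or 2 (-2.51) or the NPC library of experiment 1 (-2.80) or 4 (-2.23), or with no filter (adjusted p = 0.0569). Ly6g6e was not called with all libraries, and was without the ESC library of experiment 1 (-3.99) or 2 (-4.01). Genome-wide, the ESC libraries of experiments 1 and 2 correlated with each other at r = 0.982 across genes and those of experiments 3 and 4 at r = 0.973, against 0.933 to 0.950 between these pairs; genes are not independent replicates.

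The list's median SD over the 4 ESC libraries was 1.10 on the log2 scale, against 0.28 for all genes, at the percentile 100 of 10000 random lists matched on mean level. Library scaling was argued against, since the list's median SD was 1.11 after quantile normalization. The percentile was 100 there too, which is its ceiling and cannot show how much the spread changed. Cells of the NPC type in the ESC library with the lowest list mean were argued against, since neural progenitor transcripts stood at a median of 3.71% of their NPC level there, where 79.7% would be needed. The percentile of 100 restates the pattern, and 17 of the 36 lists reached the 95th, so it neither supports nor excludes a difference in LIF signalling between ESC cultures, which stays open. Naive pluripotency genes were at the percentile 100 too, and formative and primed epiblast genes at 99.99. The spread was thus not particular to LIF and STAT3 targets. In the ESC libraries of experiments 1 to 4 the mean log2(TPM + 1) over the naive list was 7.27, 7.19, 7.82 and 7.52. Over the epiblast list it was 4.23, 3.87, 2.71 and 2.63. A batch among ESC libraries that no label gives stays open, and the labels differ on LIF: the treatment label names 2i alone and the growth protocol names LIF beside it.

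As for chance, 35 splits of the 8 libraries into 4 and 4 were counted, the real split included. The 9333 genes called in the real split were matched by 1 of the 35, the real split itself. The highest other split called 1 gene. Every other split mixes ESC and NPC libraries, so the difference between the groups widens its error and leaves few calls by construction. With 4 against 4 libraries an exact two-sided permutation test cannot go below 0.0286. The count therefore does not exclude chance for the number of genes. The 14 lists called were matched or passed by 5 of the 35 splits, the highest other calling 16 lists, so this count does not exclude chance for the number of lists. The 4 others that reached 14 were among the 16 splits with 3 libraries of a group on a side, which keep much of the contrast between ESCs and NPCs (10 to 16 lists). The 18 splits with 2 of each group on a side called 2 to 11 lists.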
